A study of Homo sapiens with 40 samples.

How the data were processed

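A2058 cells, an established human melanoma line, were treated once with a PI3K inhibitor or with DMSO, and RNA was taken after 24 hours. Per the labels, total RNA was purified on columns, 50 ng was amplified with a linear amplification system (NuGEN Ovation), and the biotin-labelled product was hybridised to 1-colour oligonucleotide arrays with 54675 probe sets. The deposited values were intensity values, made with MAS5 according to the submitters' processing notes, with the version not given in the sources used here. The values were linear and non-negative, and the mean of each array without the highest and lowest 2% of its probe sets was 150, so each array had been scaled by a single factor. Present and absent calls were not used here, and no array was left out of the fits reported unless a sentence says so. The arrays carry no read depth, and their number, 4 per group, limits the precision.

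The 40 arrays were grouped by the compound and the concentration level in their labels, into 9 treatments and DMSO. The spelling GCD0941 was read as GDC0941, and the samples of BKM120 named IC90 (max) were used as its IC90. The gene lists, the comparisons, their tests and the rule for naming genes were fixed before the data were examined, as were the processing alternatives, except the one named as added later. The splits of the arrays and the tests of explanations for unnamed probe sets and for the array with degraded RNA were set after the main results, and before their own outcome was seen. The tests with control ratios as covariates were chosen after the results they bear on were seen.

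Of the probe sets, 41097 carried exactly 1 gene symbol, 1801 carried several and 11777 none, and 62 were array controls. Those with 1 symbol covered 19775 genes. For each gene the probe set with the highest mean log2 signal over all arrays was taken, with cross-hybridising designs used only where a gene had no other. The 11865 genes above the 40th percentile of mean signal were tested, the lowest of them at a mean signal of 13.6. Values were transformed as log2(value + 16), with no further normalization between arrays.

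Genes were tested with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 10 groups over the 40 arrays (30 residual degrees of freedom) and moderated variances with a mean-dependent trend. There were 18 comparisons: 9 of a treatment with DMSO, 6 between compounds at IC50 or IC90, and 3 of the highest with the lowest concentration of a compound. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. For a single gene, the p-value measures a change against the spread between these samples of a single cell line.

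The 18 gene lists held 668 members, 624 of them named on the array and 580 tested. They covered mitosis, DNA replication, tubulins, targets of FOXO factors and of PI3K feedback, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, ATF4 targets, ribosome biogenesis, lysosome and autophagy, p53 targets, output of MAPK signalling, the melanocyte lineage, melanoma dedifferentiation, interferon-stimulated genes, NF-kB inflammatory genes, the BCL2 family, and markers of cell types other than melanoma cells. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 162, 108 or 54 tests of its family of comparisons, and the test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. Camera compares the genes of a list with the other genes, so its p-values depend on the correlation set between genes. They do not measure the spread between arrays alone. The size of a shift is the mean log2 change over the measured members, with a 95% interval from limma on the mean log2 signal of the list in each array. The step from IC50 to IC90 was compared between BKM120 and each other compound with an interaction contrast on the scores of 5 lists, adjusted over 10 tests. Array quality was compared with DMSO by 2-sided exact permutation tests (70 arrangements, smallest p 0.0286), adjusted over 36 tests.

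Genes named in the text were eligible when their adjusted p was under 0.05 and all 4 values of one group lay beyond all 4 of the other, leaving out placeholder symbols. They were ranked by the size of the log2 change, up to 12 in each direction for the highest level of a compound against DMSO, 5 for its other levels, 8 for BKM120 against either compound at IC90, 5 for BEZ235 against GDC0941 at IC90, 4 for each pair at IC50, and 5 for the highest against the lowest level. In addition, up to 6 members of each list with the largest change, and all tubulins, could be named, and a gene named in one comparison could be given in others.

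Similarity between compounds was measured across genes as the correlation and covariance of log2 changes and as the overlap of calls, beside 100 simulations of unchanged groups against the shared DMSO arrays and beside values with the DMSO arrays split into separate pairs. The procedure was tested on simulated data with the group sizes of BKM120 IC90 (max) and DMSO. It recovered 26% of genes changed by 0.25 on the log2 scale, 72% of those changed by 0.5 and 100% of those changed by 1 or 2, with 3.25% false calls and 0 calls in an unchanged comparison.

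The alternatives tried were a pseudocount of 1 or 64, no filter on dim genes or one at the 60th percentile, quantile normalization, a replicate block, the mean over the probe sets of a gene, a fit of only the 2 groups compared, each replicate left out in turn, a 2-fold threshold, the other tests of lists, lists without members shared with another list, and split DMSO arrays. A fit of 39 arrays, without replicate 3 of BEZ235 at IC50, was added after seeing the data. Probe sets without a single gene symbol were left out of the comparisons and counted separately.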

Results

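A2058, a human melanoma cell line, was treated for 24 hours with 1 of 3 inhibitors of phosphoinositide 3-kinase (PI3K), the lipid kinase upstream of AKT, or with the solvent DMSO. BKM120 (buparlisib) inhibits the class I PI3K isoforms, BEZ235 (dactolisib) inhibits PI3K and the kinase mTOR, and GDC0941 (pictilisib), spelled GCD0941 in the sample labels, inhibits the class I PI3K isoforms. BKM120 was given at levels named IC30, IC50 and IC90 (max), and the other compounds at levels named IC50, IC90 and max. The molar concentrations, and the response that the IC levels refer to, are not given in the sources used here. Each of the 10 groups held 4 biological replicates, so that 40 one-colour oligonucleotide arrays were compared. The number of arrays limits the precision of every value. Values are log2 differences between group means of 4 arrays each, and 11865 genes were tested in each comparison.

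All 9 treatments changed the expression of many genes against DMSO, at an adjusted p under 0.05. BEZ235 at its highest level changed 6868 genes, of which 3882 rose and 2986 fell, and 517 of them changed by at least 2-fold. GDC0941 at its highest level changed 5204 genes (3022 rose, 2182 fell, 202 by at least 2-fold), and BKM120 at IC90 (max) changed 4097 (2047 rose, 2050 fell, 93 by at least 2-fold). The balance at BKM120 IC90 (max) turned with no filter on dim genes (2022 rose, 1969 fell), with the mean over probe sets (2286 rose, 2282 fell), without DMSO replicate 1, 2 or 4, and without its own replicate 2. The smallest number, 1894 genes (1164 rose, 730 fell, 23 by at least 2-fold), belonged to GDC0941 at IC50. Without 1 array with degraded RNA, replicate 3 of BEZ235 at IC50, the fit of the other 39 arrays called 2863 genes for GDC0941 at IC50, because that array widened the shared estimate of the spread. Across the 40 arrays the first principal component held 38.3% of the variance.

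**Figure D1:**
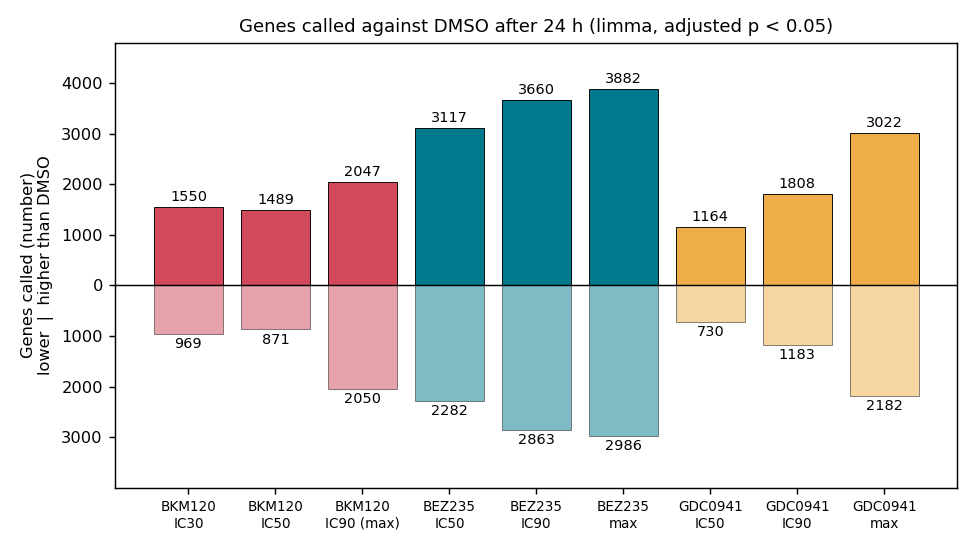
Number of genes called higher or lower than in DMSO (limma, adjusted p under 0.05) for each compound and level. BEZ235 at its highest level has the largest number, 6868, and GDC0941 at IC50 the smallest, 1894.

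The lower levels of BKM120 were compared with DMSO to find the response below its highest level. At IC30, 1550 genes rose and 969 fell. TRPM1, a melanocyte cation channel gene, rose by 1.61 (SE 0.11, n = 4), from a mean log2 signal of 6.61 in DMSO to 8.21, and MLANA, which encodes a melanosome antigen, rose by 1.32. CCN1 and CCN2, targets of the YAP and TEAD transcription factors, fell by 1.72 (SE 0.12) and fell by 1.67 (SE 0.13). At IC50, 1489 genes rose and 871 fell, with TRPM1 at 1.69, KLHL24, a FOXO-responsive gene, at 1.38 and ASNS, which encodes asparagine synthetase, at -1.56 (SE 0.10).

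Of the 25 measured genes of the melanocyte lineage, 17 rose and 0 fell at IC30, or 21 and 0 adjusted over the list alone, with a mean change of 0.41 (95% interval 0.36 to 0.45; camera adjusted p = 2.6e-13). TYR, the enzyme that starts melanin synthesis, rose by 0.79 and PMEL, a melanosome fibril protein gene, by 0.60. At IC50, 17 of these genes rose (20 adjusted over the list alone; mean 0.37). Genes linked to melanoma dedifferentiation moved the other way: 14 of 21 fell and 0 rose at IC30 (15 and 0 adjusted over the list alone), with a mean of -0.64 (95% interval -0.70 to -0.57; adjusted p = 1.0e-16). Among them THBS1, which encodes thrombospondin, fell by 1.40, NGFR, a neural crest receptor gene, fell by 1.37 and JUN, a subunit of AP-1, fell by 1.11. At IC50 the mean of this list was -0.56 and 15 members fell (16 adjusted over the list alone). Markers of other cell types stood at a mean of 0.20 at IC30 (2 of 7 rose, also adjusted over the list alone, adjusted p = 0.156) and 0.25 at IC50 (4 rose, also adjusted over the list alone, adjusted p = 0.0496, and adjusted p = 0.0724 with an estimated correlation). The IC50 call ended with no filter on dim genes (0.09, adjusted p = 0.303), a pseudocount of 1 (0.32, adjusted p = 0.0527) or 64 (0.16, adjusted p = 0.0529), quantile normalization (0.25, adjusted p = 0.0630), 39 arrays (adjusted p = 0.0650) or only these 8 arrays (adjusted p = 0.0605). It also ended without DMSO replicate 1, 3 or 4 (adjusted p = 0.0607, 0.0587 and 0.0514) and without BKM120 replicate 1, 2 or 4 (adjusted p = 0.0620, 0.0623 and 0.0603).

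Genes of cholesterol synthesis rose: 19 of 23 at IC30 (21 adjusted over the list alone) and 18 at IC50 (19 adjusted over the list alone), with means of 0.39 (95% interval 0.34 to 0.44; adjusted p = 2.2e-13) and 0.35 (adjusted p = 2.7e-11). Examples at IC30 were TM7SF2, a sterol reductase gene (0.77), SREBF2, the sterol-responsive transcription factor (0.71), and HSD17B7 (0.67). Genes of the list of FOXO targets and PI3K feedback, called FOXO-linked here, also rose. Their mean was 0.23 at IC30 (23 of 44 rose and 3 fell, 27 and 3 adjusted over the list alone, adjusted p = 1.3e-07). At IC50 it was 0.29 (25 rose and 3 fell, 30 and 3 adjusted over the list alone, adjusted p = 4.2e-10). YPEL3 rose by 1.09 at IC30, and IRS1, the insulin receptor substrate, fell by 0.61. Targets of ATF4, which controls amino acid supply, fell by a mean of 0.28 at IC30 (18 of 42 fell and 0 rose, 22 and 0 adjusted over the list alone, adjusted p = 5.6e-12). CHAC1, a glutathione-degrading enzyme gene, fell by 1.06 and SLC7A11, the cystine transporter, fell by 0.79.

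Inflammatory genes driven by NF-kB fell by a mean of 0.37 at IC30 (13 of 21 fell and 1 rose, 13 and 2 adjusted over the list alone, adjusted p = 2.9e-07), with the chemokine genes CXCL8 at -1.31 and CXCL1 at -1.16. With the dim genes under the 60th percentile left out, this mean was -0.18 (adjusted p = 0.0846). Targets of MAPK signalling fell by a mean of 0.17 at IC30 (10 of 30 fell and 2 rose, 11 and 4 adjusted over the list alone, adjusted p = 6.5e-04), with FOSL1, an AP-1 subunit, at -0.84 and the receptor gene EPHA2 at -0.88. At IC50 the MAPK mean was -0.11 (adjusted p = 0.010), and -0.09 (adjusted p = 0.0841) with that stricter filter. Mitotic genes fell by a mean of 0.16 at both levels (18 of 64 fell and 0 rose at IC30, 20 and 0 adjusted over the list alone, adjusted p = 5.7e-08, and adjusted p = 0.0519 with an estimated correlation). Lysosome genes rose by a mean of 0.19 at IC30 (25 of 53 rose and 0 fell, 28 and 1 adjusted over the list alone, adjusted p = 3.3e-06), led by the protease gene CTSF at 1.21.

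At IC90 (max), BKM120 raised mitotic genes and lowered genes of DNA replication. Of 64 mitotic genes, 56 rose and 1 fell (57 and 1 adjusted over the list alone), with a mean change of 0.52 (95% interval 0.45 to 0.59, n = 4; adjusted p = 1.6e-27). The mitotic kinase gene NEK2 rose by 1.01, the kinesin gene KIF20A by 0.94, GTSE1, which encodes a microtubule-associated protein, by 0.94, and the phosphatase gene CDC25C by 0.93. Of 62 DNA replication genes, 34 fell and 1 rose (36 and 2 adjusted over the list alone), with a mean of -0.26 (95% interval -0.31 to -0.20; adjusted p = 8.8e-09). The cyclin genes CCNE2 and CCNE1, which act at entry into S phase, fell by 1.11 and fell by 0.95, and CDC6, which loads the replicative helicase, fell by 0.91.

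Among the genes with the largest changes at IC90 (max), NT5DC4 rose by 2.10 (SE 0.11), EBLN2 by 2.07, A2M, which encodes a protease inhibitor, by 1.99, and EGR1, an immediate early transcription factor, by 1.76 (SE 0.08). MFSD2A, a lysolipid transporter gene, fell by 1.69, CHAC1 fell by 1.66, MAP2K6, a kinase of the p38 pathway, fell by 1.35, and SKP2, which directs the degradation of the inhibitor p27, fell by 1.25. FOXO-linked genes rose by a mean of 0.22 (23 of 44 rose and 8 fell, also adjusted over the list alone, adjusted p = 9.5e-05), with TXNIP, a thioredoxin-binding protein gene, at 1.65. Targets of ATF4 fell by a mean of 0.50 (31 of 42 fell and 1 rose, 32 and 1 adjusted over the list alone, adjusted p = 4.6e-16). Genes of glycolysis and hypoxia fell by a mean of 0.27 (18 of 37 fell and 1 rose, 19 and 1 adjusted over the list alone, adjusted p = 7.9e-06), with the growth factor gene VEGFA at -1.18. Melanocyte lineage genes rose by a mean of 0.23 (9 of 25 rose and 1 fell, 11 and 2 adjusted over the list alone, adjusted p = 2.6e-04). Fatty acid synthesis genes fell by a mean of 0.25 (7 of 17 fell and 0 rose, also adjusted over the list alone, adjusted p = 0.00291), with the malic enzyme gene ME1 at -1.01.

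Not called at IC90 (max) were the cholesterol list, with a mean of 0.07 (adjusted p = 0.377), the dedifferentiation list, 0.12 (adjusted p = 0.0683), and the MAPK list, 0.11 (adjusted p = 0.238), although its member FOSL1 rose by 0.91. The tubulin list fell by a mean of 0.25 (6 of 10 fell and 0 rose, also adjusted over the list alone, adjusted p = 0.00936, and adjusted p = 0.123 with an estimated correlation), with TUBB2B at -0.90 and TUBA4A at -0.70. That tubulin mean was -0.17 (adjusted p = 0.116) with the dim genes under the 60th percentile left out. Ribosome biogenesis genes fell by a mean of 0.14 (17 of 51 fell and 0 rose, 18 and 0 adjusted over the list alone, adjusted p = 0.00110, and adjusted p = 0.148 with an estimated correlation). For the interferon list (mean 0.00), the NF-kB list (mean -0.03) and the markers of other cell types (mean 0.05), none of them called, the mean, the median and the test differed in sign. Wherever else they differed in sign, the list was not called either.

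**Figure D2:**
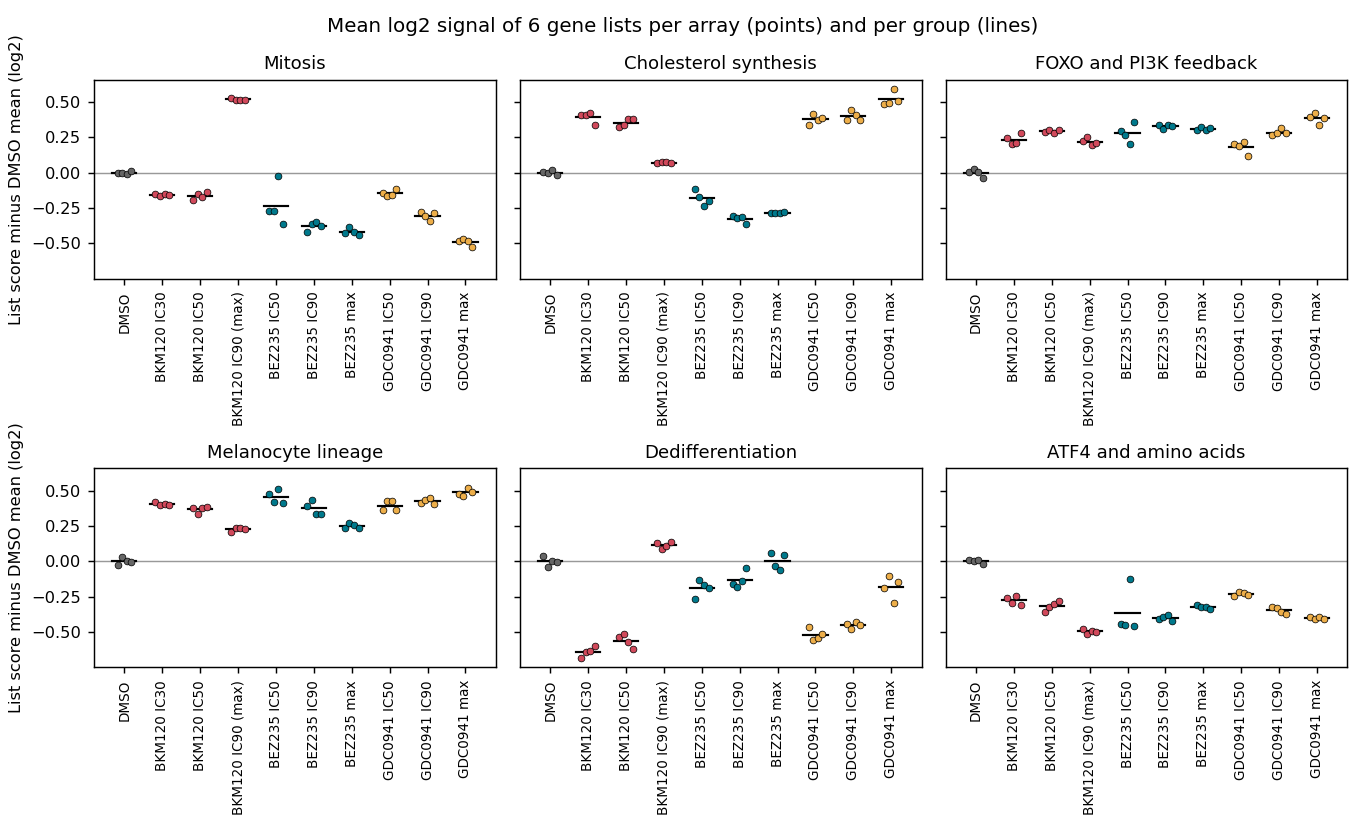
Score of 6 gene lists (mean log2 signal over the measured members, relative to the mean of the 4 DMSO arrays) in each of the 40 arrays, with a line at each group mean. The mitotic score lies above DMSO at BKM120 IC90 (max), by 0.52 on average, and below DMSO in the 8 other treatments.

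BEZ235, which also inhibits mTOR, was compared with DMSO at its 3 levels. At max, A2M rose by 2.77 (SE 0.13, n = 4), BMF, which encodes a pro-apoptotic protein, by 2.55 (SE 0.12), IL24, a cytokine gene, by 2.52, and TXNIP by 2.31 (SE 0.06), from a DMSO mean of 8.32 to 10.6. PIK3R3, a regulatory subunit gene of PI3K, fell by 2.59 (SE 0.15), the monoamine transporter gene SLC18A1 fell by 2.50, and TIGAR, a regulator of glycolysis, fell by 1.83. At IC50 and IC90, 5399 genes (3117 rose, 2282 fell) and 6523 genes (3660 rose, 2863 fell) changed. With only the 8 arrays of BEZ235 IC50 and DMSO fitted, the degraded one among them, the IC50 count was 2223 (1299 rose, 924 fell). With the mean over probe sets more genes fell than rose at IC50 (2520 rose, 2864 fell).

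Sterol genes fell with BEZ235. Cholesterol synthesis genes fell by a mean of 0.18 at IC50 (10 of 23 fell and 4 rose; adjusted p = 0.00332), 0.33 at IC90 (12 fell and 4 rose; adjusted p = 7.8e-04) and 0.28 at max (10 fell and 3 rose; adjusted p = 0.00322), with the same counts adjusted over the list alone. At IC90 the sterol transfer protein gene STARD4 fell by 1.80, ACAT2 fell by 1.41, and HMGCS1, which makes the first committed intermediate of the pathway, fell by 0.97. The mean at IC50 was -0.11 (adjusted p = 0.0542) with the dim genes under the 60th percentile left out. Fatty acid synthesis genes fell by means of 0.23, 0.37 and 0.36 at the 3 levels, and at IC90 12 of 17 fell and 0 rose, also adjusted over the list alone (adjusted p = 3.5e-04). The elongase gene ELOVL6 fell by 0.92 and SREBF1, the lipogenic transcription factor, fell by 0.90.

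Mitotic genes fell by means of 0.23, 0.38 and 0.42 at IC50, IC90 and max of BEZ235. At max 51 of 64 fell and 1 rose (52 and 1 adjusted over the list alone, adjusted p = 9.6e-13), with the checkpoint kinase gene BUB1 at -0.78. DNA replication genes fell by a mean of 0.25 at max (37 of 62 fell and 7 rose, also adjusted over the list alone, adjusted p = 6.4e-06, and adjusted p = 0.0519 with an estimated correlation), while CDT1, a licensing factor gene, rose by 1.24. Tubulin genes fell by a mean of 0.62 at IC90 (9 of 10 fell and 0 rose, also adjusted over the list alone; 95% interval -0.70 to -0.55; adjusted p = 1.1e-05), with TUBB2B at -1.44 and TUBA1A at -1.33. At IC50 the tubulin mean was -0.32 (5 of 10 fell; adjusted p = 0.00142, and adjusted p = 0.0597 with an estimated correlation). TUBB3 stood at 0.04, or -0.17 after quantile normalization, and TUBB at -0.13, or 0.06 as a mean over its probe sets. Without the degraded array, replicate 3, the IC50 means were -0.30 for the mitotic list and -0.40 for the tubulin list.

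FOXO-linked genes rose by means of 0.28, 0.33 and 0.31 at the 3 levels of BEZ235, and at max 29 of 44 rose and 11 fell (30 and 11 adjusted over the list alone, adjusted p = 0.00128). KLHL24 rose by 1.94, and SESN3, a stress-response gene, fell by 2.10. Targets of ATF4 fell by a mean of 0.40 at IC90 (28 of 42 fell and 2 rose, also adjusted over the list alone, adjusted p = 7.2e-08), with ASNS at -1.58. Targets of p53 fell by a mean of 0.26 at max (11 of 22 fell and 2 rose, 12 and 2 adjusted over the list alone, adjusted p = 0.00647), where CYFIP2 rose by 1.17. Interferon-stimulated genes rose by a mean of 0.31 at max (19 of 36 rose and 4 fell, 19 and 5 adjusted over the list alone, adjusted p = 0.00417, and adjusted p = 0.0558 with an estimated correlation), with the antiviral gene RSAD2 at 1.02 and GBP1 at -1.03. Melanocyte lineage genes rose by a mean of 0.45 at IC50 (18 of 25 rose and 1 fell, 19 and 1 adjusted over the list alone, adjusted p = 1.2e-08). At max their mean was 0.25 (adjusted p = 0.0695).

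The dedifferentiation list was not called at any level of BEZ235 (means -0.19, -0.13 and 0.00; adjusted p = 0.0834, 0.478 and 0.762), and at IC90 its median was 0.10 while its mean was negative. NGFR fell by 1.45 at IC50 and FN1, the fibronectin gene, rose by 0.62. The NF-kB list fell by a mean of 0.22 at IC50 (10 of 21 fell and 4 rose, also adjusted over the list alone, adjusted p = 0.0393), and the call ended in other fits. The mean was -0.18 (adjusted p = 0.0937) without replicate 3 of BEZ235 and -0.21 without DMSO replicate 1 (adjusted p = 0.0567) or replicate 3 (adjusted p = 0.0577). With the dim genes under the 60th percentile left out it was 0.05 (adjusted p = 0.837), as a mean over probe sets -0.19 (adjusted p = 0.139), and with a pseudocount of 1 it was -0.28 (adjusted p = 0.0511). Lysosome genes rose by a mean of 0.20 at IC50 (26 of 53 rose and 8 fell, also adjusted over the list alone, adjusted p = 0.00311, and adjusted p = 0.185 with an estimated correlation), with CTSF at 1.89. Without the degraded array, replicate 3, this lysosome mean was 0.14 (camera adjusted p = 0.00733).

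GDC0941 changed 1894, 2991 (1808 rose, 1183 fell) and 5204 genes at IC50, IC90 and max. DHRS3, a retinaldehyde reductase gene, showed the largest fall of any gene named by the selection rule, by 3.31 at max (SE 0.13, n = 4), from a DMSO mean of 9.67 to 6.36, and it fell by 2.53 at IC90. BMF rose by 2.21 at max, CTSF by 2.12 and A2M by 1.89. The interleukin receptor gene IL7R fell by 1.94 and CXCL8 fell by 1.63.

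Cholesterol synthesis genes rose with GDC0941 by means of 0.38, 0.40 and 0.52 at the 3 levels, and at max 19 of 23 rose and 0 fell, also adjusted over the list alone (95% interval 0.47 to 0.57; adjusted p = 6.6e-09). TM7SF2 rose by 1.47, SREBF2 by 1.18 and SQLE, the squalene epoxidase gene, by 0.78. Mitotic genes fell by means of 0.15, 0.30 and 0.49, and at max 54 of 64 fell and 1 rose (57 and 1 adjusted over the list alone, adjusted p = 5.3e-23), with the kinesin gene KIF18A at -0.91. DNA replication genes fell by a mean of 0.22 at max (32 of 62 fell and 3 rose, also adjusted over the list alone, adjusted p = 3.3e-07), and tubulin genes by a mean of 0.32 (8 of 10 fell and 2 rose, also adjusted over the list alone, adjusted p = 3.6e-04).

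FOXO-linked genes rose by means of 0.18, 0.28 and 0.38, and at max 29 of 44 rose and 5 fell (31 and 5 adjusted over the list alone, adjusted p = 4.7e-07), with KLHL24 at 1.72 and YPEL3 at 1.70. Melanocyte lineage genes rose by means of 0.40, 0.43 and 0.49, and at max 19 of 25 rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 3.4e-08). Dedifferentiation genes fell by means of 0.52 at IC50 (16 of 21 fell and 0 rose, 17 and 0 adjusted over the list alone, adjusted p = 4.6e-16) and 0.45 at IC90 (adjusted p = 4.8e-10). At max their mean was -0.18 (adjusted p = 0.0423, and adjusted p = 0.142 with an estimated correlation). That call ended with the dim genes under the 60th percentile left out (-0.09; adjusted p = 0.359), without members shared with another list (-0.16; adjusted p = 0.0803) and with only these 8 arrays (adjusted p = 0.0518). It also ended without DMSO replicate 1 (-0.17; adjusted p = 0.0624) or 3 (-0.18; adjusted p = 0.0575) or without replicate 1 (-0.18; adjusted p = 0.0599) or 3 (-0.15; adjusted p = 0.0834) of GDC0941. NF-kB genes fell by means of 0.36, 0.36 and 0.43 (adjusted p = 5.9e-08, 2.8e-06 and 8.2e-05). These means were -0.11, -0.14 and -0.09 with the dim genes under the 60th percentile left out (adjusted p = 0.116, 0.177 and 0.561). At IC50 the MAPK list fell by a mean of 0.16 (9 of 30 fell and 0 rose, 11 and 1 adjusted over the list alone, adjusted p = 8.3e-05). The BCL2 family list was not called at max (mean 0.23; adjusted p = 0.450), although its members BMF and HRK, both pro-apoptotic, rose by 2.21 and 1.33. Markers of other cell types stood at a mean of 0.32 at IC90 (3 of 7 rose, also adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.0502 with an estimated correlation). The receptor gene PDGFRA stood at 0.76, the collagen gene COL3A1 at 0.63 and the proteoglycan gene DCN at 0.45. This mean was 0.30 without replicate 4 of GDC0941 (adjusted p = 0.0534) and 0.10 with no filter on dim genes (adjusted p = 0.451).

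The series compares distinct PI3K inhibitors, so the compounds were set against each other at the nominal levels they share. BKM120, a morpholino pyrimidine, and GDC0941, a thienopyrimidine with a morpholine ring, differed least at IC50: 71 genes were called, 54 higher and 17 lower with BKM120, and 0 by at least 2-fold, in the limma fit. DHRS3 was higher with BKM120 by 0.93 (SE 0.13, n = 4; adjusted p = 1.9e-04), and CGA, a glycoprotein hormone subunit gene, was lower (log2 difference -0.61), as was the neurofilament gene NEFL (-0.43). The share of called genes that were higher was 76.1%, and it was 65.7% of 137 genes after quantile normalization. The count of 71 was 490 without the degraded array, 350 with only these 8 arrays and 37 with the mean over probe sets, of which 17 were higher and 20 lower. It was 36, 27 and 47 without BKM120 replicates 1, 2 and 4, and 32, 35, 118 and 18 without GDC0941 replicates 1, 2, 3 and 4.

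At IC50, FOXO-linked genes were higher with BKM120 than with GDC0941 by a mean of 0.11 (95% interval 0.06 to 0.16; 5 of 44 higher and 0 lower, 8 and 0 adjusted over the list alone, adjusted p = 7.1e-05). Glycolysis and hypoxia genes were lower by a mean difference of -0.11 (95% interval -0.16 to -0.06; 1 of 37 lower, 5 adjusted over the list alone, adjusted p = 8.8e-06). The cholesterol list differed by -0.02 (95% interval -0.07 to 0.02; adjusted p = 0.305), the mitotic list by -0.02 (95% interval -0.08 to 0.05; adjusted p = 0.312) and the melanocyte lineage list by -0.03 (95% interval -0.07 to 0.02; adjusted p = 0.243).

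BEZ235, an imidazoquinoline, differed from both at IC50, with 3825 genes against BKM120 (1836 higher and 1989 lower with BKM120) and 4021 against GDC0941 (2163 higher and 1858 lower with BEZ235). Cholesterol synthesis genes were higher with BKM120 than with BEZ235 by a mean of 0.53 (95% interval 0.48 to 0.58; 16 of 23 higher and 0 lower, also adjusted over the list alone, adjusted p = 1.9e-15). They were lower with BEZ235 than with GDC0941 by a mean difference of -0.56 (95% interval -0.61 to -0.51; 17 of 23 lower and 0 higher, also adjusted over the list alone, adjusted p = 8.1e-16). STARD4 differed by 1.44 (SE 0.08) between BKM120 and BEZ235. MAPK targets were higher with BEZ235 than with GDC0941 by a mean of 0.28 (18 of 30 higher and 1 lower, also adjusted over the list alone, adjusted p = 1.1e-05), with EGR1 at 1.04. They were lower with BKM120 than with BEZ235 (mean difference -0.23; adjusted p = 1.7e-04). CCN2 and CCN1 were lower with BKM120 than with BEZ235, with differences of -1.41 and -1.32. Dedifferentiation genes were also lower with BKM120 than with BEZ235 (mean difference -0.37; 13 of 21 lower and 0 higher, 15 and 0 adjusted over the list alone, adjusted p = 1.2e-06). Tubulin genes were higher with BKM120 than with BEZ235 by a mean of 0.28 (3 of 10 higher, 4 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.171 with an estimated correlation). TUBA1C, TUBB3 and TUBB4B stood at -0.03, -0.04 and -0.01, or 0.11, 0.12 and 0.10 after quantile normalization, and TUBB at 0.09, or -0.14 as a mean over its probe sets. That call ended with the mean over probe sets (0.24; adjusted p = 0.134) and without replicate 1 of BEZ235 (0.26; adjusted p = 0.0589). With only the 8 arrays of each pair, the degraded one among them, the counts were 817 (438 higher and 379 lower with BKM120) and 1020. The balance of both comparisons turned with the mean over probe sets, to 2169 higher and 1514 lower with BKM120 and to 1795 higher and 2249 lower with BEZ235. It also turned without the degraded array, replicate 3 of BEZ235, to 1930 and 1758 and to 1944 and 2051.

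At IC90, mitotic genes separated BKM120 from both other compounds. They were higher at BKM120 IC90 (max) than at BEZ235 IC90 by a mean of 0.89 (95% interval 0.83 to 0.96, n = 4; 63 of 64 higher and 1 lower, also adjusted over the list alone, adjusted p = 3.2e-47). They were higher than at GDC0941 IC90 by 0.82 (95% interval 0.75 to 0.89; 61 of 64 higher and 0 lower, 62 and 0 adjusted over the list alone, adjusted p = 2.8e-60). GTSE1 differed by 1.73 and 1.42, and the centromere motor gene CENPE was higher by 1.29 than with GDC0941. NT5DC4 and EBLN2 were higher with BKM120 than with BEZ235 by 2.34 and 2.29, and than with GDC0941 by 2.39 and 2.17. In all, 5360 genes differed between BKM120 and BEZ235 (2195 higher and 3165 lower with BKM120) and 3564 between BKM120 and GDC0941 (1388 higher and 2176 lower), the last count being 2343 with the dim genes under the 60th percentile left out.

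DNA replication genes were lower with BKM120 than with GDC0941 (mean difference -0.20, 95% interval -0.25 to -0.14; 28 of 62 lower and 6 higher, also adjusted over the list alone, adjusted p = 2.7e-04, and adjusted p = 0.145 with an estimated correlation), with CCNE1 at -1.04. This set the highest level of BKM120 against a level of GDC0941 below its highest. Relative to DMSO the replication score was -0.26 at BKM120 IC90 (max), -0.06 at GDC0941 IC90 and -0.22 at GDC0941 max. Against BEZ235 the replication list differed by -0.02 (95% interval -0.07 to 0.04; adjusted p = 0.712), while its median was 0.04. Cholesterol synthesis genes were ordered GDC0941, BKM120, BEZ235: the mean was -0.33 for BKM120 minus GDC0941 (95% interval -0.38 to -0.28; 15 of 23 lower and 0 higher, 16 and 0 adjusted over the list alone, adjusted p = 9.9e-07). It was 0.40 for BKM120 minus BEZ235 (95% interval 0.35 to 0.45; 14 of 23 higher and 2 lower, 15 and 2 adjusted over the list alone, adjusted p = 6.1e-07). FOXO-linked genes differed by -0.11 between BKM120 and BEZ235 (95% interval -0.16 to -0.06; camera adjusted p = 0.197) and by -0.07 between BKM120 and GDC0941 (95% interval -0.12 to -0.02; adjusted p = 0.739), neither list being called. Dedifferentiation genes were higher with BKM120 than with GDC0941 by a mean of 0.57 (15 of 21 higher and 0 lower, 16 and 1 adjusted over the list alone, adjusted p = 2.2e-12), with the signal transducer gene SMAD3 at 0.96. The tubulin list was higher with BKM120 than with BEZ235 by a mean of 0.37 (95% interval 0.29 to 0.44; 6 of 10 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.00279, and adjusted p = 0.0975 with an estimated correlation). In it TUBB stood at 0.01, or -0.13 as a mean over its probe sets. Between BKM120 and GDC0941 the tubulin list was not called (mean difference -0.16, 95% interval -0.23 to -0.08; adjusted p = 0.489).

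BEZ235 and GDC0941 differed in 5100 genes at IC90 (2724 higher and 2376 lower with BEZ235, or 1734 and 1784 with the dim genes under the 60th percentile left out). Cholesterol synthesis genes were lower with BEZ235 by a mean difference of -0.73 (95% interval -0.77 to -0.68; 18 of 23 lower and 1 higher, also adjusted over the list alone, adjusted p = 7.1e-14), with STARD4 at -2.11 and HMGCS1 at -1.68. PIK3R3 differed by -2.38 (SE 0.15) and TUBA1A by -1.86. The tubulin list was lower with BEZ235 by a mean difference of -0.52 (95% interval -0.60 to -0.45; 7 of 10 lower, also adjusted over the list alone, adjusted p = 1.6e-04), as was the DNA replication list (-0.18, 95% interval -0.24 to -0.13; 29 of 62 lower and 3 higher, also adjusted over the list alone, adjusted p = 7.7e-05, and adjusted p = 0.106 with an estimated correlation). The mitotic list differed by -0.07 (95% interval -0.14 to 0.00; adjusted p = 0.0698). It was called with no filter on dim genes (adjusted p = 0.0148), with the mean over probe sets (-0.09; adjusted p = 0.0195) and with only these 8 arrays (adjusted p = 0.0454). It was also called without BEZ235 replicate 2 (-0.08; adjusted p = 0.0485) and without GDC0941 replicate 3 (-0.09; adjusted p = 0.0378). Targets of p53 were lower with BEZ235 (mean difference -0.25; 10 of 22 lower and 1 higher, also adjusted over the list alone, adjusted p = 0.00350), with the cell cycle inhibitor gene CDKN1A at -0.92. Markers of other cell types were lower with BEZ235 by a mean difference of -0.43 (5 of 7 lower, also adjusted over the list alone, adjusted p = 0.0127), or -0.14 with no filter on dim genes (adjusted p = 0.116).

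The highest level of each compound was compared with its lowest to follow the response with concentration. Between IC30 and IC90 (max) of BKM120, 1696 genes were higher and 2340 lower at the higher level, or 2684 in all with the dim genes under the 60th percentile left out. CCN1 was higher at the higher level by 2.20, and FGFBP3, which encodes a binding protein of fibroblast growth factors, was lower (log2 difference -1.86). Mitotic genes were higher by a mean of 0.67 (58 of 64 higher and 0 lower, 59 and 0 adjusted over the list alone, adjusted p = 2.3e-42) and dedifferentiation genes by 0.76 (15 of 21 higher and 0 lower, 17 and 1 adjusted over the list alone, adjusted p = 7.5e-15). Cholesterol genes were lower (mean difference -0.32; 15 of 23 lower and 0 higher, 16 and 0 adjusted over the list alone, adjusted p = 3.3e-06). For BEZ235, 2419 genes were higher and 2217 lower at max than at IC50, or 1792 in all with only those 8 arrays fitted. This balance turned with quantile normalization (2206 higher, 2334 lower), with the dim genes under the 60th percentile left out (1517 higher, 1825 lower) and without BEZ235 IC50 replicate 4. IL24 was higher by 2.10, PIK3R3 lower (-1.71), and DNA replication genes lower (mean difference -0.23; 36 of 62 lower and 1 higher, also adjusted over the list alone, adjusted p = 2.9e-08). Without the degraded array, a replicate of BEZ235 IC50, this DNA replication difference was -0.18 (camera adjusted p = 4.8e-07). Markers of other cell types were lower too (mean difference -0.40, 4 of 7 lower, also adjusted over the list alone, adjusted p = 0.00979), or -0.15 with no filter on dim genes (adjusted p = 0.0398). For GDC0941, 1918 genes were higher and 1590 lower at max than at IC50, or 1189 and 1231 with the dim genes under the 60th percentile left out. DHRS3 was lower (-2.66), mitotic genes were lower (mean difference -0.34; 47 of 64 lower and 1 higher, 52 and 1 adjusted over the list alone, adjusted p = 2.2e-21), and dedifferentiation genes were higher by a mean of 0.34 (9 of 21 higher and 1 lower, 10 and 1 adjusted over the list alone, adjusted p = 4.8e-04).

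The step from IC50 to IC90 was compared directly between compounds for 5 lists. For mitotic genes the step was 0.68 with BKM120, and it exceeded that of BEZ235 by 0.82 (95% interval 0.73 to 0.92; adjusted p = 4.2e-20). It exceeded that of GDC0941 by 0.84 (95% interval 0.74 to 0.93; adjusted p = 4.2e-20). For cholesterol genes the BKM120 step of -0.28 differed by -0.14 from that of BEZ235 (adjusted p = 5.6e-04; -0.04 and adjusted p = 0.338 with the dim genes under the 60th percentile left out) and by -0.30 from that of GDC0941 (adjusted p = 1.7e-10). For FOXO-linked genes the differences of steps were -0.12 against BEZ235 (adjusted p = 0.00176) and -0.18 against GDC0941 (adjusted p = 1.5e-05), the last with an adjusted p = 0.0784 when probe sets were averaged. For DNA replication genes they were -0.01 (adjusted p = 0.833) and -0.20 (95% interval -0.28 to -0.12; adjusted p = 1.2e-05), and for tubulin genes 0.09 (adjusted p = 0.142) and -0.07 (adjusted p = 0.230). The BKM120 step ended at its highest level. At GDC0941 max, outside this test, the DNA replication score relative to DMSO was -0.22, near the -0.26 of BKM120 IC90 (max). Without the degraded array the DNA replication step against BEZ235 differed by -0.06 (adjusted p = 0.0164) and the tubulin step against GDC0941 by -0.07 (adjusted p = 0.0219). The tubulin step against BEZ235 differed by 0.11 without BEZ235 IC50 replicate 1 (adjusted p = 0.0482) and by 0.13 without its replicate 4 (adjusted p = 0.0226). It differed by 0.11 with a pseudocount of 64 (adjusted p = 0.0347) and by 0.23 with the stricter filter (adjusted p = 0.00415).

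Across genes, the changes against DMSO of BKM120 and GDC0941 at IC50 correlated at 0.803. All treatments shared the 4 DMSO arrays, which alone gave a correlation of 0.499 in 100 simulations without any treatment effect, and with the DMSO arrays split into separate pairs the value was 0.655. With groups of equal size the simulated correlation is about 0.50 by construction, so it does not measure the part of the shared arrays in an observed correlation. The split leaves fewer DMSO arrays behind each change, and the added noise also lowers a correlation. The covariance for BKM120 and GDC0941 at IC50 was 0.0386, or 0.0342 with the split, against 0.00559 in the simulations. At IC50 it was 0.0463 for BKM120 and BEZ235, against 0.00564 simulated, and 0.0394 for BEZ235 and GDC0941, against 0.0056 simulated. The other correlations, with the simulated and the split values, were 0.617, 0.501 and 0.527 for BKM120 and BEZ235 at IC50, and 0.560, 0.498 and 0.466 for BEZ235 and GDC0941 at IC50. At IC90 they were 0.567, 0.501 and 0.515 for BKM120 and BEZ235, 0.438, 0.50 and 0.360 for BKM120 and GDC0941, and 0.619, 0.499 and 0.553 for BEZ235 and GDC0941. At IC90 the covariances were 0.0733, 0.0336 and 0.0675, against 0.00564, 0.00563 and 0.00561 simulated. Genes are not independent replicates, so these values describe the profiles and carry no test.

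The genes called in both treatments of a pair, in the same direction, were counted beside the number that independent calls would give. At IC50, BKM120 and GDC0941 shared 843 genes that rose (146.1 if independent) and 452 that fell (53.6), and 0 genes moved in opposite directions (177.1). BKM120 and BEZ235 shared 1045 (391.2) and 551 (167.5), with 70 in opposite directions (515.2), and BEZ235 and GDC0941 shared 794 (305.8) and 432 (140.4), with 78 (415.6). At IC90, BKM120 and BEZ235 shared 1374 genes that rose (631.4) and 1209 that fell (494.7), with 346 in opposite directions (1126). BKM120 and GDC0941 shared 844 (311.9) and 590 (204.4), with 249 (516.5), and BEZ235 and GDC0941 shared 1304 (557.7) and 851 (285.5), with 161 (801.2). The shared controls add to these overlaps.

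Signs of RNA quality and scaling were measured on each array. The log2 ratio of the 3′ to the 5′ control probe set of ACTB averaged 0.855 ± 0.135 (SD, n = 4) in DMSO. It was higher at all 3 levels of BEZ235, at 1.94 ± 1.81 for IC50, 1.17 ± 0.033 for IC90 and 1.08 ± 0.081 for max, and the 3 exact permutation tests gave p = 0.0286, the smallest possible (adjusted p = 0.343 over 36 tests). The list changes of BEZ235 against DMSO were not refitted with these ratios as covariates. Replicate 3 of BEZ235 at IC50 read 4.65 for ACTB and 1.77 for GAPDH. Its correlation with the other arrays of its group was 0.952. At BKM120 IC90 (max) the ACTB ratio was 0.825 ± 0.044 and the median log2 signal 4.97 ± 0.013, against 4.86 ± 0.071 in DMSO (exact permutation p = 0.0857; adjusted p = 0.588). A share of 52.3% of the probe sets read at or below a signal of 16 in the DMSO arrays, and 50.5% at BKM120 IC90 (max).

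**Figure D3:**
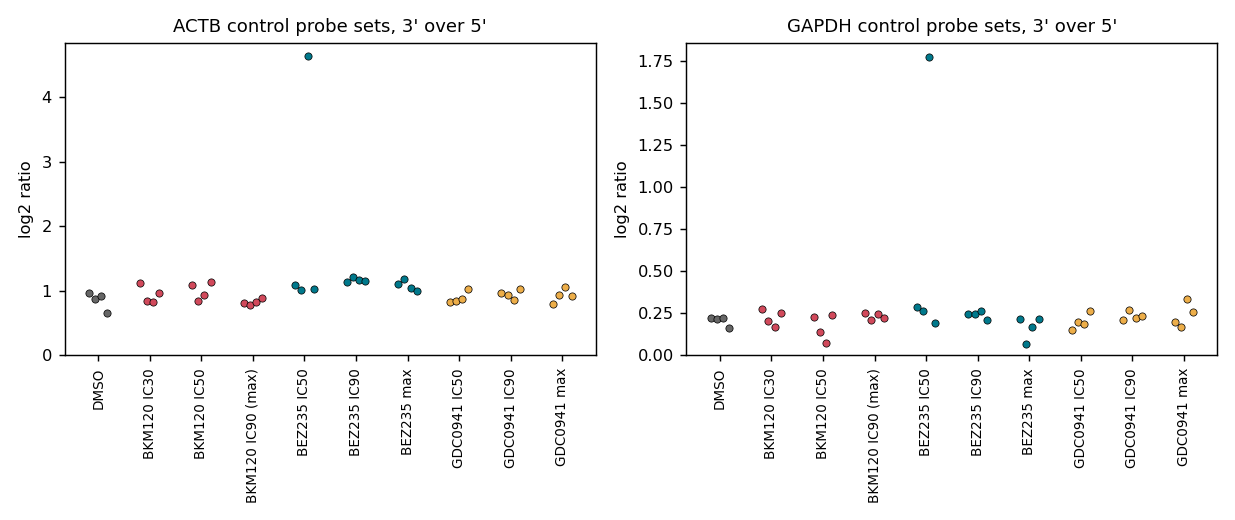
Log2 ratio of the 3′ to the 5′ control probe sets of ACTB and GAPDH in each of the 40 arrays, by group. Replicate 3 of BEZ235 at IC50 lies apart from the other arrays, at 4.65 for ACTB and 1.77 for GAPDH.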

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

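Most tests were set before their own outcome was seen, those of the unnamed probe sets, of the degraded array and of the splits after the main results; the tests of both RNA-quality explanations with control ratios as covariates, the fit of 39 arrays, and the reasons given for leaving the tubulin and mislabelling explanations open were chosen only after the results were seen.

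The rise of mitotic genes from IC50 to IC90 stood out with BKM120, because its step exceeded that of BEZ235 by 0.82 and that of GDC0941 by 0.84. Array scaling is argued against, since the smaller ratio of the list difference after quantile normalization to that on the deposited scale was 1.01. RNA quality met the mark written beforehand only formally, the ACTB ratio of 0.825 lying just below the range of the other groups (0.855 to 1.94; GAPDH 0.232 within 0.167 to 0.627), and it is argued against by the later test, where the smaller list difference with both ratios as covariates was 0.832. Depolymerised tubulin was to lower tubulin genes below their level with both other compounds, whereas the tubulin list was higher than with BEZ235 (0.37, 95% interval 0.29 to 0.44) and lower than with GDC0941 (-0.16, 95% interval -0.23 to -0.08), so the bound written beforehand against it was passed. It was nevertheless left open, a reason given after these values were seen, because BEZ235 itself lowered the tubulin list where its mitotic list fell (-0.32 and -0.23 at IC50), so a mitotic arrest through tubulin cannot be told apart from another difference between the compounds or between their doses, which were matched only by name. The lower tubulin level than with GDC0941 was not seen at GDC0941 max. Relative to DMSO the tubulin score was -0.32 there and -0.25 at BKM120 IC90 (max), while the mitotic scores were -0.49 and 0.52.

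Probe sets without a single gene symbol gave a signal outside the comparisons: of 3977 tested, 218 were at least 2-fold higher than in DMSO at BKM120 IC90 (max), against 88 at BEZ235 max and 33 at GDC0941 max. The 218 probe sets had a median DMSO log2 signal of 5.40, against 6.49 for all those tested, and 19 of them carried several symbols. Scaling is argued against by the 202 counted after quantile normalization, and RNA quality by the 229 counted with the control ratios as covariates. A background raised alike on all those tested is argued against by their median difference of 0.0428. That median covers brighter probe sets than the 218 and does not bear on a rise confined to dim ones. The median log2 signal over all probe sets was 4.97 at BKM120 IC90 (max), the highest of the 10 groups, and 4.86 in DMSO. In the 8 other treatments the median change of the 218 lay between -0.23 and -0.05. No biological explanation was tested, and the probe sets stay unnamed here.

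Replicate 3 of BEZ235 at IC50 stood apart from the other 39 arrays, with log2 ratios of 3′ to 5′ control probe sets of 4.65 for ACTB and 1.77 for GAPDH and a DNA replication score of 0.13 far from the other replicates. Degraded RNA fits, since the array's step from the middle to the 5′ probe set of ACTB was 3.10, with the other arrays between 0.367 and 0.674, and its other 3 steps were also the highest. Scaling is argued against, because the array's mean correlation with its group after quantile normalization was 0.951, with the lowest array outside the group at 0.993. A mislabelled sample stays open: the array's change from DMSO correlated most with the other BEZ235 IC50 arrays (0.462), which passed the bound written beforehand, but nearly as much with BEZ235 IC90 (0.454), a margin considered only after the values were seen.

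The concentration steps of other lists also differed between BKM120 and another compound in the direct test: by -0.20 for DNA replication genes against GDC0941, by -0.12 and -0.18 for FOXO-linked genes against BEZ235 and GDC0941, and by -0.14 and -0.30 for cholesterol genes. At GDC0941 max, outside that test, the DNA replication score relative to DMSO was -0.22, near the -0.26 of BKM120 IC90 (max). The other outlying arrays were replicate 4 of BKM120 IC30 (median log2 signal 4.94, 51.1% of probe sets at or below 16, cholesterol score 0.33), replicate 1 of BKM120 IC50 (4.94 and 51.2%) and DMSO replicate 4 (GAPDH ratio 0.160). In all, 9 of 90 groups of values held an outlying array, and chance gives about 1 in 20, or 4.5.

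Every count of called genes was compared with the counts from all 35 splits of its 8 arrays into 4 and 4, and in each of the 18 comparisons only 1 of 35 splits, the real one, called as many. With 4 arrays in each group a share of 1 in 35 is the smallest possible. Against DMSO, the real count and the highest of the other splits were 2519 and 59, 2360 and 12, and 4097 and 11 for BKM120 at IC30, IC50 and IC90 (max). They were 5399 and 2049, 6523 and 990, and 6868 and 1275 for BEZ235, and 1894 and 11, 2991 and 14, and 5204 and 841 for GDC0941, in order of level. Between compounds at IC50 they were 3825 and 1691 for BKM120 with BEZ235, 71 and 0 for BKM120 with GDC0941, and 4021 and 1961 for BEZ235 with GDC0941. At IC90 they were 5360 and 21, 3564 and 8, and 5100 and 6 for the same pairs, and between the highest and lowest levels 4036 and 426 for BKM120, 4636 and 1895 for BEZ235, and 3508 and 572 for GDC0941.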

How the results depend on the processing

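The fit without the degraded array was chosen only after the data were seen; all other alternatives were planned. What limits the results is the number of arrays, 4 per group, and the background of the signal, with 52.3% of probe sets at or below 16 in DMSO. A pseudocount of 1 or 64 and no filter on dim genes left all 18 counts of called genes within 1.5 times their value. Of the 144 counts obtained with 1 replicate left out, 137 stayed within that range. Where no cause is given, the cause was not tested.

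With a 2-fold threshold added, which by construction counts fewer genes, the counts were 39, 31 and 93 for BKM120 at IC30, IC50 and IC90 (max), 124, 400 and 517 for BEZ235 and 23, 55 and 202 for GDC0941 against DMSO. They were 34, 0 and 47 for BKM120 with BEZ235, BKM120 with GDC0941 and BEZ235 with GDC0941 at IC50, 208, 120 and 146 for these pairs at IC90, and 140, 100 and 42 for the highest against the lowest level of BKM120, BEZ235 and GDC0941. Without the degraded array the counts were 2863 for GDC0941 at IC50 against DMSO and 490 for BKM120 with GDC0941 at IC50. That last comparison, with 71 genes, gave 137 after quantile normalization, 37 with the mean over probe sets, 350 with only its 8 arrays fitted, and 18 to 118 with 1 replicate left out, moving in 7 of 8 such fits. With only the 2 groups fitted, the degraded array among them, the counts were 2223 for BEZ235 IC50 against DMSO, 817 and 1020 for BEZ235 IC50 with BKM120 and with GDC0941, and 1792 for BEZ235 max against IC50. The filter at the 60th percentile, which tests fewer genes, gave 2343 for BKM120 with GDC0941 at IC90 and 2684 for the highest against the lowest level of BKM120.

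For the 5 lists of the concentration steps, compared between compounds at IC90, an estimated correlation ended 3 calls without changing their shift: tubulin for BKM120 minus BEZ235 (0.37, adjusted p = 0.0975), and DNA replication for BKM120 minus GDC0941 (-0.20, adjusted p = 0.145) and BEZ235 minus GDC0941 (-0.18, adjusted p = 0.106). Over all 18 lists and all comparisons it ended 69 calls. Fry, which does not compare a list with other genes, called FOXO-linked genes for BKM120 minus BEZ235 (-0.11, adjusted p = 1.4e-07) and BEZ235 minus GDC0941 (0.0439, adjusted p = 5.3e-06), tubulin for BKM120 minus GDC0941 (-0.16, adjusted p = 0.0120) and mitosis for BEZ235 minus GDC0941 (-0.0722, adjusted p = 0.0343). The latter was also called with no filter (-0.0722, adjusted p = 0.0148), the mean over probe sets (-0.0926, adjusted p = 0.0195) and only 2 groups (-0.0722, adjusted p = 0.0454), and ranged from -0.085 to -0.0583 with 1 replicate left out. The filter at the 60th percentile called FOXO-linked genes for BEZ235 minus GDC0941 (0.0666, adjusted p = 0.0383).

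Of the concentration steps, that of DNA replication against BEZ235 was called without the degraded array (-0.0594, adjusted p = 0.0164), and ranged from -0.0594 to 0.0166 with 1 replicate left out. That of tubulin was called against GDC0941 without the degraded array (-0.0678, adjusted p = 0.0219), and against BEZ235 with a pseudocount of 64 (0.11, adjusted p = 0.0347) and the 60th percentile filter (0.23, adjusted p = 0.00415), ranging from 0.00561 to 0.125 with 1 replicate left out. Those of FOXO-linked genes against GDC0941 with the mean over probe sets (-0.11, adjusted p = 0.0784) and of cholesterol against BEZ235 with the 60th percentile filter (-0.0446, adjusted p = 0.338) were no longer called. With the DMSO arrays split, which removes the shared controls, the correlations were 0.527 for BKM120 with BEZ235 and 0.655 with GDC0941 at IC50, and 0.515, 0.360 and 0.553 for the pairs at IC90. The split also leaves fewer DMSO arrays behind each change, and the added noise lowers a correlation too. The covariance of BKM120 and GDC0941 at IC50 was 0.0342 with the split and 0.0386 without it.

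Directions reversed in 14 results. The NF-kB list at BEZ235 IC50 stood at 0.0452 with the 60th percentile filter, which leaves out its dim members. With the mean over probe sets, which adds other probe sets of a gene, HK2 stood at 0.0417 at BKM120 IC50 and 0.22 at BEZ235 max, BCL2L11 at -0.15 at BEZ235 IC50, -0.0907 at GDC0941 IC90 and -0.14 for BEZ235 minus GDC0941 at IC50, and TUBB at 0.0595 at BEZ235 IC50 and -0.14 and -0.13 for BKM120 minus BEZ235 at IC50 and IC90. With quantile normalization TUBB3 stood at -0.17 at BEZ235 IC50, 0.12 for BKM120 minus BEZ235 and -0.13 for BEZ235 minus GDC0941 at IC50, and TUBA1C and TUBB4B at 0.11 and 0.0953 for BKM120 minus BEZ235 at IC50.

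With the replicate number as a replicate block, all 18 counts stayed within 1.5 times their value, all 324 list tests kept their side of the threshold, and of the results for single genes, each a gene in 1 comparison, 14 lost and 5 gained a call, 2127 being the same. Arrays of the same number did not pair, with a mean residual correlation of -0.01.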

Other observations

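No explanation was tested in this part, and its genes come from the fixed lists, except DHRS3, which was named by its rank. Among ribosome biogenesis genes, BEZ235 at max raised NOB1, which encodes a factor of small subunit maturation, by 1.15 and POLR1E, a subunit gene of RNA polymerase I, by 0.90, while PNO1, another maturation factor gene, fell by 0.79. The list as a whole was not called (14 of 51 rose and 7 fell, 13 and 7 adjusted over the list alone; mean 0.05; adjusted p = 0.904). MYC, the growth-promoting transcription factor, rose by 0.94 at BEZ235 max and by 1.26 at GDC0941 max. At BKM120 IC90 (max) the lysosomal enzyme gene GLA fell by 0.68 and the autophagy kinase gene ULK1 rose by 0.79, in a lysosome list that was not called (mean 0.10; adjusted p = 0.0698).

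Glycolysis and hypoxia genes fell by a mean of 0.22 at BEZ235 IC90 (15 of 37 fell and 3 rose, also adjusted over the list alone; adjusted p = 0.00312, and adjusted p = 0.123 with an estimated correlation), with the aldolase gene ALDOC at -1.10 and the glucose transporter gene SLC2A1 at -1.01. At GDC0941 max the mean was -0.21 (14 of 37 fell and 2 rose, also adjusted over the list alone; adjusted p = 0.00114, and adjusted p = 0.0905 with an estimated correlation), with SLC2A1 at -1.16. PMAIP1, a pro-apoptotic member of the BCL2 family list, fell by 0.78 at BKM120 IC90 (max), by 1.01 at BEZ235 max and by 0.80 at GDC0941 max, and BCL2, an anti-apoptotic member, rose by 0.47 at BKM120 IC90 (max) and by 0.43 at GDC0941 max. The response of DHRS3 differed between compounds at IC90, where it was higher with BKM120 than with GDC0941 by 2.55 and higher with BEZ235 than with GDC0941 by 1.65.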
